A study of Mus musculus with 11 samples.

How the data were processed

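Total RNA of 11 mouse cell samples was measured on Affymetrix whole-transcript gene arrays, 1 array per sample. Per the labels' protocols, embryonic fibroblasts carrying a doxycycline-controlled activator (rtTA) at the Rosa locus were infected with viruses for Klf4, Oct4 (Pou5f1), Myc and Sox2 under a doxycycline promoter. Day 0 was the day doxycycline was added, 1 day after infection. Cells were sorted at day 6 and day 9 on CD73 (gene Nt5e) or CD49d (gene Itga4), and the labels call CD49d+ and CD73+ cells poised and CD73- cells non-poised. Unsorted cells of both days and 3 control samples were also measured: uninfected mouse embryonic fibroblasts (MEF), a partially reprogrammed cell line (SC4) and V6.5 mouse embryonic stem cells (ESC). RNA was prepared with an RNeasy Mini kit with on-column DNase and labelled with the GeneChip WT Terminal Labeling kit, per the labels' protocols.

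The deposited values are intensities for 41345 probe sets on the 11 arrays, in 1 table. Partek is named, without a version, in the submitters' processing notes. The summarisation, background correction and scaling between arrays are not given in the sources used here. The deposited intensities are linear and none lies below 100, a floor that holds 52.14% to 54.31% of the probe sets of each array. The 99th percentile of intensity ran from 4732.3 to 4970.6 over the arrays and the highest intensity from 13433.5 to 14765. No scaling was added in the main analysis. The test had been planned on log2 values, so log2 of the deposited intensity was taken first. A value at the floor is only an upper bound. Where 1 side of a comparison lay at the floor on all its arrays the fold is given as at least that value, and no fold is given where both sides did. Where only some arrays of a side did, the fold is given as fitted and may understate the difference.

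Probe sets were named from the platform annotation held by GEO, with symbols updated through gene identifiers in a RefSeq gene table of assembly GRCm38.p6, which was used for names only. One symbol was listed for 23521 probe sets, several for 1814 and none for 16010, and only the first kind was used in the comparisons. They name 22180 genes, of which 1082 have more than 1 probe set. A gene with several was represented by the probe set of highest mean over the 11 arrays. The filter kept genes whose highest array lay above the median of all values, which proved to be the floor. Between 11824 and 12633 named genes (53.31% to 56.96%) lay above the floor on a given array. The filter left 14301 genes, of which 988 were at the floor on all 8 reprogramming arrays and 13313 were tested.

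Each of the 11 groups (a population at a day, or a control) has 1 array and no group has a replicate. The 8 reprogramming arrays were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on terms for the 4 populations and the 2 days, which leaves 3 residual degrees of freedom per gene with a prior of 2.12. The error is thus the disagreement of a population difference between day 6 and day 9. Nothing in the labels says that the cultures of the 2 days were separate, so the p-values of population contrasts measure only agreement between days, which may be days of the same culture. For day 9 minus day 6 the error is the disagreement of the day difference among the 4 populations. These are not replicates of a day. Contrasts were the mean of CD49d+ and CD73+ minus CD73-, each pair of sorted populations, each sorted population minus unsorted cells, and day 9 minus day 6. A gene passed at a Benjamini-Hochberg adjusted p under 0.05, and ± marks the standard error (SE) of a log2 difference from this fit. Differences between 2 single arrays carry no test and were counted at 1 log2 unit (2-fold) or more. The position of an array between MEF and ESC is the median over genes of its log2 difference from MEF divided by the ESC minus MEF difference, for genes at least 2 log2 units apart, without Pou5f1, Sox2, Klf4 and Myc. Intervals of a position are 95% rank intervals across genes, which are not independent replicates.

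Before the data were examined, 25 gene lists, the contrasts, the filter, the tests, the alternatives and the rule for naming genes were fixed. The reprogramming factors (Pou5f1, Sox2, Klf4, Myc) and the sorting markers (Nt5e, Itga4) are given gene by gene. The other 23 lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. In the latter setting camera also uses only the 3 residual degrees of freedom of the fit. A call lost there need not come from correlated members. They are the pluripotency network, epithelial junction and keratin genes, mesenchymal and fibroblast genes, TGF-beta response genes, cell cycle S phase, cell cycle G2 and M phase, p53 and senescence genes, glycolysis, oxidative phosphorylation, interferon response, FGF-ERK response genes, immediate early and heat shock genes, Hox genes, germ cell genes, DNA and histone modifiers, epidermal genes, primitive endoderm and mesendoderm genes, trophoblast genes, neural genes, macrophage and blood cell markers, endothelial markers, skeletal muscle markers, and surface markers used in reprogramming. Of 691 list genes, 647 had a probe set with 1 symbol, 5 of them through a gene identifier, and 532 were among the tested genes. For single arrays a list median is given as a percentile among 10000 random lists matched on mean expression in 20 bins, as a description of these arrays.

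The genes named are Nt5e, Itga4, Pou5f1, Sox2, Klf4, Myc, Nr0b1 and Etv5 in any case. For poised minus CD73- they are the 10 highest and 10 lowest genes by fitted difference among those at least 1 log2 unit apart in the same direction for CD49d+ and for CD73+ at both days. For every other contrast they are the 5 highest and 5 lowest at least 1 log2 unit apart one way at both days, or in all 4 populations for the day contrast. They are the 10 highest and 10 lowest for ESC minus MEF, 6 and 6 for SC4 against either control, and from each list up to 4 members of largest absolute poised minus CD73- difference and up to 3 for the day contrast. Predicted genes, microRNAs, small nucleolar RNAs and olfactory receptors were skipped in the ranked parts, and genes named outside the rule are marked as chosen after their values were seen.

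The fit was tested on simulated data with noise drawn from the moderated standard deviations, which is somewhat optimistic. For poised minus CD73- over 13313 genes, it recovered 51 of 67 genes changed 1.5-fold (76.1%), 64 of 67 changed 2-fold (95.5%) and 66 of 66 changed 4-fold. Of 186 calls 5 were false (2.69%). The changed genes, and the simulated lists, were drawn only from genes with a geometric mean more than 2-fold above the floor. Recovery of dimmer genes was thus not tested. Camera called 0 of 100 unchanged lists of 25 genes and called a list raised by 0.5 log2 units. The noise was drawn independently for each gene, so false calls from correlated members could not arise in this simulation. In the data the estimated correlation was 0.77 for G2 and M phase and 0.406 for FGF-ERK response genes. The simulation therefore does not show how often such lists are called falsely. For arrays, the number of arrays limits the precision.

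Alternatives were quantile normalization, centring each array on the median of its tested genes, no filter, a filter at the 75th percentile, the mean of a gene's probe sets, eBayes with an intensity trend and a robust prior, the 6 sorted arrays only, no block term for day or population, and leaving out each of the 8 arrays in turn. Without the filter the same 13313 genes were fitted, since constant genes were dropped, and only the adjustment ran over all 22180 genes. Single-array counts were repeated at 1.5-fold and 3-fold, and list tests also with unmatched random lists. A fit on the 11066 genes above the floor on all 8 arrays was added after the data had been seen. Probe sets with no symbol or several symbols were left out of the comparisons because they name no single gene. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.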

Results

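Gene expression was measured on 11 arrays to compare cell populations sorted early in the reprogramming of mouse fibroblasts by Klf4, Oct4, Myc and Sox2. The 8 reprogramming arrays hold CD49d+, CD73+, CD73- and unsorted cells at day 6 and at day 9. The other 3 hold mouse embryonic fibroblasts (MEF), the partially reprogrammed line SC4 and embryonic stem cells (ESC). Each group has 1 array, so no group has a replicate, and the spread in the limma and camera tests of the main fit is the disagreement between the 2 days. The median intensity of probe sets above the floor ran from 347.05 to 388.34 over the arrays.

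The sorting markers followed the sort labels at both days. Nt5e, which encodes the ectonucleotidase CD73, had intensities of 3438 and 3658 in CD73+ cells and 2828 and 2704 in CD49d+ cells at days 6 and 9, against 331.9 and 292.4 in CD73- cells. Unsorted cells lay between, at 1207 and 1669, and MEF, SC4 and ESC had 495.3, 3738 and 249.5. Itga4, which encodes the integrin chain CD49d, had 1859 and 1588 in CD49d+ cells and 1082 and 1206 in CD73+ cells, against 152.7 and 169.6 in CD73- cells and 332.6 in MEF. Among the reprogramming factors, Klf4, a zinc finger factor, had 3476 to 4134 on all 8 reprogramming arrays against 704.5 in MEF and 834 in ESC. Poised and CD73- cells differed in Klf4 by 0.09 ± 0.0615 log2 units (SE), which did not pass (limma, adjusted p = 0.404). Myc, a growth regulator, had a difference of -0.09 ± 0.165 (adjusted p = 0.773). The probe set of Pou5f1 stayed near the floor on every array, with 122.7 even in ESC, and that of Sox2 lay at 100 on every array but ESC, where it had 3829. Pou5f1 levels could not be read from its probe set, and whether these probe sets detect the introduced copies is not given in the sources used here.

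Poised cells, taken as CD49d+ and CD73+ together, differed from CD73- cells by up to 11.4-fold among the named genes. Besides Nt5e (10.1-fold higher, log2 3.33 ± 0.141, adjusted p = 0.00243) and Itga4 (8.71-fold, 3.12 ± 0.143, adjusted p = 0.0031), on which the cells were sorted, the thyrotropin-releasing hormone precursor Trh was 11.4-fold higher (3.51 ± 0.467, adjusted p = 0.0167). The transglutaminase Tgm3 was 11.2-fold higher (3.49 ± 0.127, adjusted p = 0.00243), the matrix protein gene Sbspon 11.1-fold (3.48 ± 0.263), the G protein subunit Gna14 10.9-fold (3.45 ± 0.337) and the Tec family kinase Bmx 9.73-fold (3.28 ± 0.0899). The kallikrein Klk1 was at least 9.57-fold higher, being at the floor in CD73- cells, and the neurokinin precursor Tac2 7.79-fold. Nr0b1, an orphan nuclear receptor of the stem cell network, was 7.52-fold higher (2.91 ± 0.265, adjusted p = 0.00768), and the ETS family factor Etv5 3.47-fold (1.80 ± 0.261, adjusted p = 0.0201). Lower in poised cells were the small proteoglycan Ogn (6.96-fold, -2.80 ± 0.241, adjusted p = 0.00696), Fndc3c1 (5.73-fold), the fibulin Efemp1 (4.86-fold), the growth factor Fgf15 (4.45-fold), the LIM cofactor Ldb2 (4.06-fold) and the imprinted gene Phlda2 (3.96-fold). The cerebellin Cbln2 (3.91-fold), the neprilysin gene Mme (3.74-fold), the receptor Tnfrsf19 (3.69-fold) and the glypican Gpc3 (3.55-fold) were lower as well.

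The direction of these differences was shared by the 2 days. Of 14301 genes, 186 were at least 2-fold higher in poised cells at both days and 59 at least 2-fold lower, where independent lists would share 5.75 and 0.958, and 0 went opposite ways. The differences of the 2 days, which share no array, correlated at r = 0.80 across genes, which are not independent replicates. Taking CD49d+ and CD73+ cells apart, 121 genes other than predicted genes and short RNAs were at least 2-fold higher and 36 lower in both populations at both days. In limma 1599 of 13313 genes passed (Benjamini-Hochberg), 953 higher and 646 lower, of which 251 and 80 differed at least 2-fold, and 4055 genes had an unadjusted p under 0.05. With each array centred on its median, 48.2% of the genes that passed were higher, against 59.6% as deposited. Without a filter on dim probe sets 994 genes passed, where the same 13313 genes were fitted and only the adjustment ran over 22180 genes. The count rests on single arrays: it was 786 without the day 6 CD49d+ array, 250 without day 6 CD73+, 51 without day 6 CD73-, and 1 (Bmx) without day 6 unsorted. It was 213 without day 9 CD73+, 131 without day 9 CD73-, 570 without day 9 unsorted and 1775 without day 9 CD49d+. Without 1 array the fit has 2 residual degrees of freedom in place of 3. The unsorted arrays are on neither side of this contrast, and on the 6 sorted arrays, also with 2 residual degrees of freedom, 1087 genes passed. The eBayes prior degrees of freedom were 2.28 there, 1.1 without day 6 unsorted and 1.61 without day 9 unsorted. The low counts without an unsorted array thus go with the prior of the spread, since the differences themselves do not change.

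**Figure D1:**
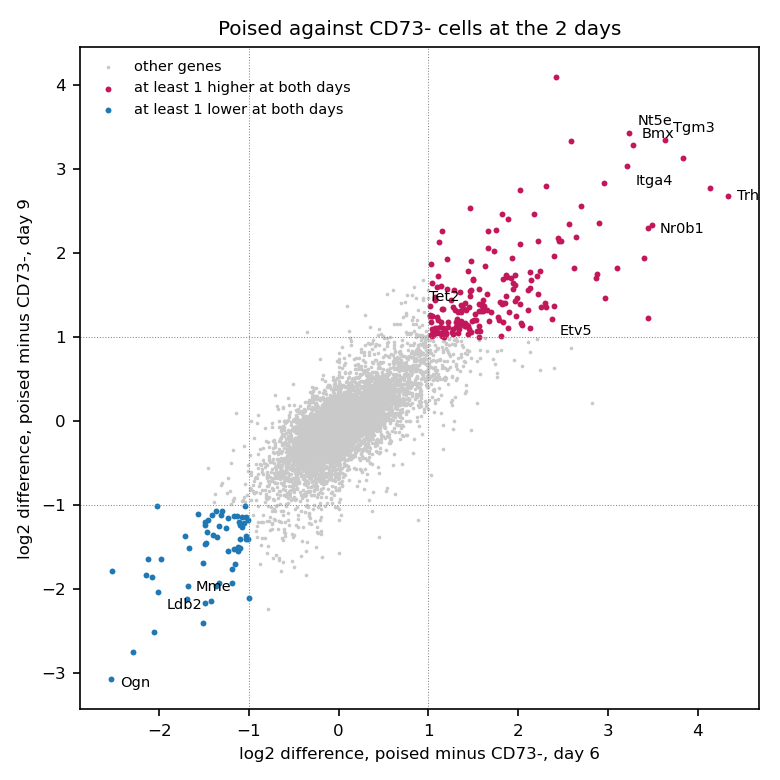
Each point is a gene, with the log2 difference of poised (mean of CD49d+ and CD73+) minus CD73- cells at day 6 on the horizontal axis and at day 9 on the vertical axis. Coloured points are the 186 genes at least 1 log2 unit higher and the 59 at least 1 lower at both days, and 0 coloured or other points lie past 1 in opposite directions.

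**Figure D2:**
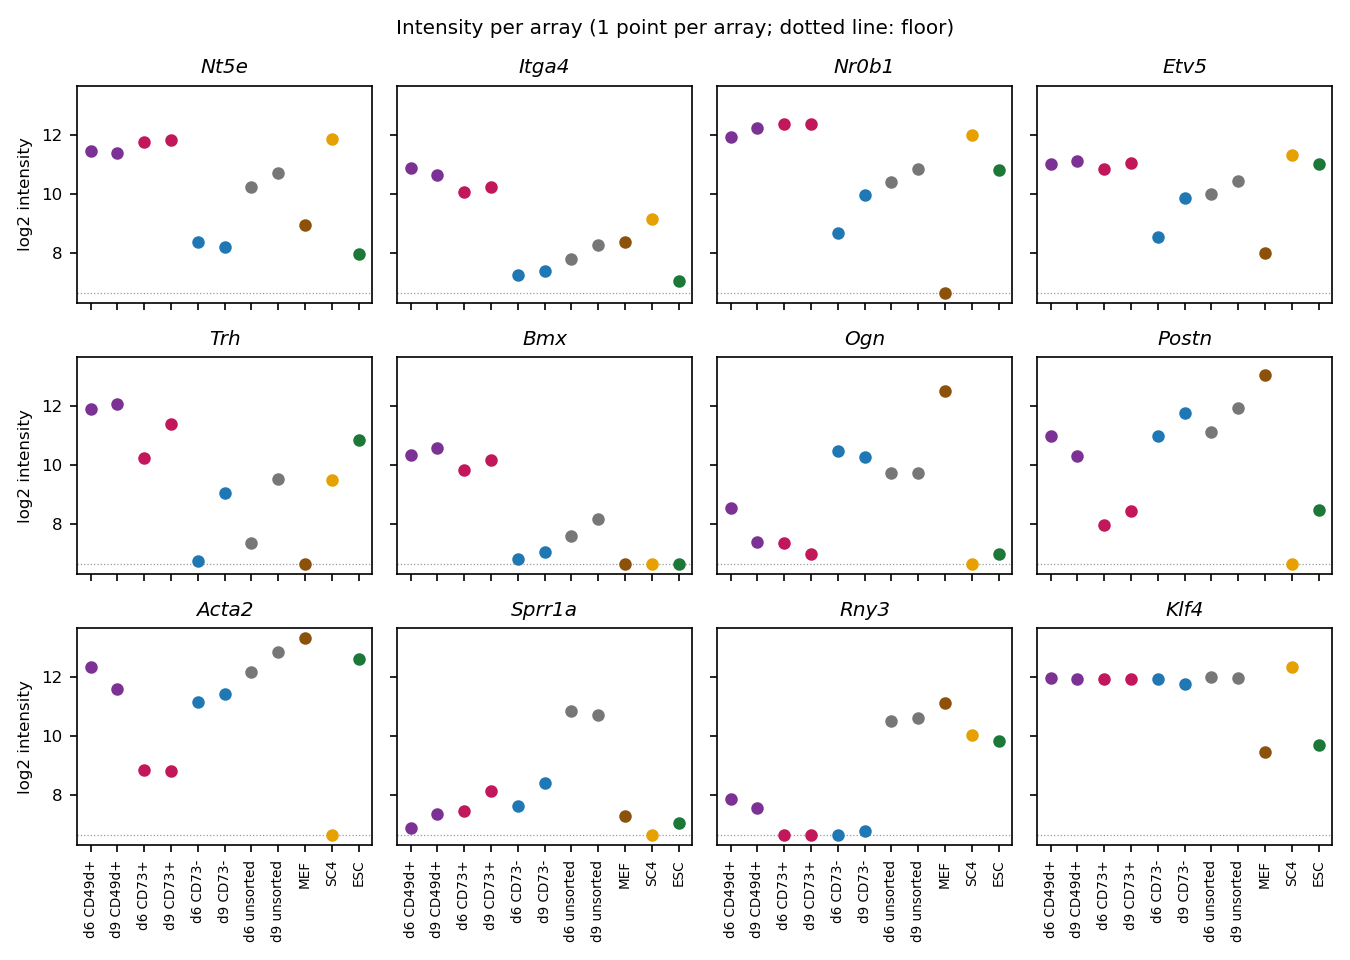
Points are log2 intensities of 12 genes on each of the 11 arrays, 1 point per array, with the floor as a dotted line. Nt5e, Itga4, Nr0b1, Etv5, Trh and Bmx are higher in CD49d+ and CD73+ than in CD73- cells at both days, Acta2 is lowest among reprogramming arrays in CD73+ cells (8.86 and 8.81), and Rny3 is above 10.5 in unsorted cells and below 7.9 on the 6 sorted arrays.

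A total of 4 gene lists shifted between poised and CD73- cells. FGF-ERK response genes (camera, adjusted p = 0.000552), epithelial junction and keratin genes (adjusted p = 0.00618) and surface markers used in reprogramming (adjusted p = 0.0255) were higher, and cell cycle S phase genes were lower (adjusted p = 0.031). None of the 4 passed when the correlation among members was estimated (adjusted p = 0.991 with an estimated correlation for each). That setting also lowers the degrees of freedom of the test to 3. The estimated correlations ran from 0.0645 for epithelial to 0.687 for S phase genes. The lost calls thus do not show correlated members as their cause. Among 17 FGF-ERK response genes, 4 rose and 0 fell over all genes tested, and 10 rose and 0 fell adjusted over the list alone. They include Spry4, a feedback inhibitor of the pathway (log2 1.87 ± 0.214, adjusted p = 0.0115), Etv5 and the phosphatase Dusp4 (1.02, adjusted p = 0.0171), while the phosphatase Dusp6 stood at 1.14 (adjusted p = 0.0637). Of 32 epithelial genes 7 rose and 2 fell (11 and 2 adjusted over the list alone). The desmosome gene Dsp (1.27, adjusted p = 0.00445), the epithelial factor Ehf (1.21, adjusted p = 0.0247) and the protease inhibitor Spint1 (1.17, adjusted p = 0.0167) were higher and the cadherin Cdh3 was lower (-1.31, adjusted p = 0.031). Of 26 surface markers 7 rose and 1 fell (11 and 2 adjusted over the list alone), among them the integrin Itgb4 (1.33), podoplanin (Pdpn, 1.02) and Cd200 (0.90), with the alkaline phosphatase Alpl at 1.51 without passing (adjusted p = 0.0729). Of 39 S phase genes 0 rose and 2 fell, the helicase Hells (-0.44, adjusted p = 0.0483) and the cyclin Ccne1 (-0.31, adjusted p = 0.0289), and 0 and 0 passed adjusted over the list alone. The epithelial call ended without the day 9 CD73- array (adjusted p = 0.118) and without the day term (0.0891). That of the surface markers ended without day 6 CD49d+ (0.154), day 6 CD73- (0.0569) or the day term (0.0966), and that of S phase without day 6 CD49d+ (0.294), day 6 CD73- (0.146), day 9 CD73+ (0.104) or day 9 CD73- (0.0827) and under quantile normalization (0.0698, with a median of -0.14 where that of all tested genes moved from -0.0102 to -0.0226). Over all alternatives the adjusted p ran from 1.59e-05, 8.11e-05, 0.00216 and 5.07e-05 for these lists, in the order of the calls, up to 0.991.

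The other 19 lists were not called in this contrast. Of 29 pluripotency network genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; camera, adjusted p = 0.233). The growth factor Fgf4 (1.61, adjusted p = 0.00476) and L1td1 (1.59, adjusted p = 0.00392) were higher beside Nr0b1 and Etv5, and Utf1, a chromatin factor of stem cells, was lower (-1.06, adjusted p = 0.0144). Of 44 mesenchymal and fibroblast genes 4 rose and 5 fell (4 and 6 over the list alone). They include periostin (Postn, -1.95, adjusted p = 0.0284), biglycan (Bgn, -1.17, adjusted p = 0.0296) and the collagen Col3a1 (-1.13, adjusted p = 0.0189), all lower, while the lysyl oxidase relative Loxl1 stood at -0.98 (adjusted p = 0.129). Of 10 trophoblast genes 1 rose and 5 fell, both ways of adjusting, including the imprinted gene Peg10 (-1.34, adjusted p = 0.00656), the homeobox gene Esx1 (-1.16) and the helix-loop-helix factor Ascl2 (-0.95). Among 30 DNA and histone modifiers 4 rose and 1 fell, both ways of adjusting, with the methylcytosine oxidase Tet2 higher (adjusted p = 0.00476). The demethylase Kdm3a (0.42) and the Polycomb partner Jarid2 (0.45) were higher and the Polycomb subunit Eed was lower (-0.48). Of 18 immediate early and heat shock genes 2 rose and 2 fell (2 and 3 over the list alone), the stress gene Gadd45b (-1.58, adjusted p = 0.00768) and Atf3 (-0.83) being lower, the nuclear receptor Nr4a1 higher (0.99) and Jun at -0.63 (adjusted p = 0.062).

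Among 24 p53 and senescence genes 3 rose and 2 fell (5 and 2 adjusted over the list alone), with Igfbp3 (1.02), Ptprv (0.71) and the retinoblastoma gene Rb1 (0.59) higher and Perp at 0.66 (adjusted p = 0.0711). Of 20 epidermal genes 1 rose and 2 fell, both ways of adjusting, with the glutathione transferase Gsta4 at 1.26, Krtdap at -1.34 and the desmocollin Dsc3 at -0.57, each past the threshold, and Sprr1a at -0.56 (adjusted p = 0.135). Of 16 neural genes 2 rose and 0 fell (3 and 2 over the list alone), Crmp1 at 1.41 and Stmn2 at 0.72, with neurofilament Nefl at 1.73 (adjusted p = 0.0635) and Fabp7 at 1.52 (adjusted p = 0.166) not passing. Of 11 endothelial markers 3 rose and 1 fell, both ways of adjusting, with the angiopoietin receptor Tek at 1.30, Ecscr at 0.62 and Cldn5 at 0.52. Of 7 macrophage and blood cell markers Laptm5 alone rose (1.17, adjusted p = 0.00856), both ways of adjusting. Of 20 TGF-beta response genes 2 rose and 0 fell (1 and 0 over the list alone), with Bhlhe40 at 0.92, and thrombospondin Thbs1 at -1.10 (adjusted p = 0.146) and Tgfbi at -0.71 (adjusted p = 0.129) did not pass. Glycolysis (18 genes, 1 rose, the aldolase Aldoc at 1.86, adjusted p = 0.00737, also adjusted over the list alone) and interferon response (27 genes, 1 rose, 0 over the list alone) were not called either. In the latter Oas2 stood at 1.81 (adjusted p = 0.131) and Xaf1 at 1.05 (adjusted p = 0.103). In the remaining 6 lists, Hox genes (29), cell cycle G2 and M phase (51), oxidative phosphorylation (47), germ cell genes (5), primitive endoderm and mesendoderm genes (12) and skeletal muscle markers (11), limma called 0 members over all genes and 0 over the list alone. At an unadjusted p under 0.05 stood 5 G2 and M phase and 6 oxidative phosphorylation genes, all lower, 1 higher and 3 lower Hox genes and 1 higher endoderm gene. Median, mean and test differed in sign for TGF-beta, p53, glycolysis, immediate early, epidermal and skeletal muscle lists, none of which was called.

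CD73+ cells were also set against CD73- cells alone, the 2 sides of the CD73 sort. Nt5e (11.4-fold, log2 3.51 ± 0.163, adjusted p = 0.00603), Gna14 (11.4-fold, 3.51 ± 0.389), Sbspon (11.3-fold), Klk1 (at least 10.4-fold) and Nr0b1 (8.32-fold, adjusted p = 0.0141) were highest. Ogn (9.09-fold, -3.18 ± 0.278, adjusted p = 0.012), Postn (8.99-fold, -3.17 ± 0.387, adjusted p = 0.0187), the retinoic acid binding protein Crabp1 (7.43-fold), Efemp1 (6.28-fold) and tenascin C (Tnc, 5.79-fold, adjusted p = 0.0462) were lowest. At least 2-fold differences of one direction at both days were found for 192 higher and 89 lower genes, with 6.54 and 1.35 for independent lists, 0 opposite and r = 0.80 across genes. In limma 1065 genes passed, 673 higher and 392 lower, and 3721 had an unadjusted p under 0.05. Under quantile normalization 50.9% of passing genes were higher, against 63.2%. The unsorted arrays are on neither side of this contrast either, so leaving 1 out alters only the spread with its prior, not the differences. The count fell to 0 (limma, Benjamini-Hochberg) without day 6 CD73+, day 6 CD73-, day 6 unsorted, day 9 CD73+ or day 9 CD73- and to 2 without day 9 unsorted, with 1900 to 3971 genes at an unadjusted p under 0.05 when an array was left out. It was 918 without day 6 CD49d+ and 1009 without day 9 CD49d+, 1735 with centring, 616 on the 6 sorted arrays, 612 without the day term and 497 without a filter.

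Between CD73+ and CD73- cells 8 lists were called, 3 of them higher: FGF-ERK response (camera, adjusted p = 0.00669), epithelial (adjusted p = 0.0265) and surface markers (adjusted p = 0.0451). Mesenchymal (adjusted p = 0.023), trophoblast (adjusted p = 0.0265), G2 and M phase (adjusted p = 0.0265), S phase (adjusted p = 0.0451) and oxidative phosphorylation genes (adjusted p = 0.0451) were lower, and each of the 8 had adjusted p = 0.997 with an estimated correlation. Of 44 mesenchymal genes 3 rose and 6 fell (4 and 14 adjusted over the list alone), with a list median of -0.50. Smooth muscle actin (Acta2, -2.46, adjusted p = 0.0234) and Bgn (-2.04, adjusted p = 0.0172) fell beside Postn. The homeobox genes Meox2 (1.03) and Prrx1 (0.87) and the T-box gene Tbx15 (0.71), factors of mesenchymal development, were higher. FGF-ERK members were 3 higher and 0 lower (5 and 0 adjusted over the list alone), and Spry4 stood at 1.69 (adjusted p = 0.0275). Epithelial members were 5 and 1 (8 and 2 over the list alone), surface markers 3 and 1 (10 and 1), trophoblast genes 0 and 4 (0 and 5) and S phase genes 0 and 1 (0 and 0). Among G2 and M phase and oxidative phosphorylation genes limma called 0 members (0 over the list alone), with 4 and 9 lower at an unadjusted p under 0.05. The FGF-ERK call was kept without any 1 array. The mesenchymal call ended without day 6 CD73+ (adjusted p = 0.0742) or day 9 CD73- (0.1) and under quantile normalization (0.0616), and the epithelial call without day 9 CD73- (0.286). The surface marker call ended without any 1 array other than day 9 CD73+ (0.0665 to 0.0872). That of trophoblast genes ended without day 6 CD73+, day 6 CD73-, day 6 unsorted or day 9 unsorted (0.0554 to 0.0742), and that of G2 and M phase ended without day 6 CD73- (0.089), day 9 CD73+ (0.205) or day 9 CD73- (0.0752). S phase (0.0655 to 0.237) and oxidative phosphorylation calls (0.068 to 0.109) ended without day 6 CD73-, day 6 unsorted, day 9 CD73+, day 9 CD73- or day 9 unsorted. Quantile normalization ended the trophoblast (0.0546), S phase (0.112), G2 and M phase (0.087) and oxidative phosphorylation calls (0.112). The medians of these and of the mesenchymal list stood at -0.54, -0.16, -0.14, -0.10 and -0.54 under it, while that of all tested genes moved from -0.0191 to -0.0573. Relative to all tested genes, the S phase, G2 and M phase and oxidative phosphorylation shifts were smaller under it. Leaving out the day term ended the epithelial (0.208), surface marker (0.257) and oxidative phosphorylation calls (0.09). The lowest adjusted p over all alternatives was 0.00137 for FGF-ERK response and mesenchymal genes, 0.000661 for epithelial genes and 0.0451 for oxidative phosphorylation, and the highest 0.997 for each.

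CD49d+ cells against CD73- cells shared part of these differences. Trh (17.1-fold, log2 4.09 ± 0.54, adjusted p = 0.0168), Tgm3 (15.7-fold, 3.97 ± 0.146, adjusted p = 0.00327), Bmx (11.4-fold, adjusted p = 0.00327), Sbspon (11-fold) and Itga4 (10.7-fold, 3.42 ± 0.165) were highest. Fndc3c1 (6.3-fold, adjusted p = 0.0203), Ogn (5.33-fold, adjusted p = 0.0132), Fgf15 (4.59-fold), the amino acid transporter Slc7a2 (3.96-fold) and the cornified envelope gene Cnfn (3.87-fold, adjusted p = 0.0268) were lowest. At both days 207 genes were at least 2-fold higher and 63 lower, with 8.73 and 1.65 for independent lists, 1 opposite and r = 0.74 across genes. The CD73- arrays serve both poised contrasts, so part of any overlap on 1 day may come from shared arrays, but comparisons of different days share none. The 2 gates may still hold some of the same cells. Nt5e had intensities of 2828 and 2704 in CD49d+ cells, and Itga4 1082 and 1206 in CD73+ cells, at days 6 and 9. Overlap across days is thus not agreement of 2 populations known to be separate. CD73+ minus CD73- at day 6 and CD49d+ minus CD73- at day 9 had 149 genes at least 2-fold higher in both (6.11 for independent lists) and 58 lower (1.44), with r = 0.56 across genes. With the days exchanged they had 195 (9.34) and 51 (1.55), with r = 0.64. In limma 1777 genes passed, 1024 higher and 753 lower, with 4118 at an unadjusted p under 0.05, and 44.9% were higher with centring against 57.6%. Here too, leaving out an unsorted array alters only the spread with its prior, not the differences. The count was 101 without day 6 CD49d+, 274 without day 6 CD73+, 69 without day 6 CD73-, and 1 without day 6 unsorted. It was 350 without day 9 CD73+, 111 without day 9 CD73-, 601 without day 9 unsorted, 1203 without day 9 CD49d+, 1183 on the 6 sorted arrays and 1007 without a filter.

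FGF-ERK response genes (camera, adjusted p = 0.00106), epithelial genes (adjusted p = 0.00398) and surface markers (adjusted p = 0.0161) were the lists called, all higher in CD49d+ than in CD73- cells, each with adjusted p = 0.968 with an estimated correlation. FGF-ERK members were 5 higher and 0 lower (10 and 0 adjusted over the list alone), Spry4 at 2.04 and Dusp5 at 0.61 among them. Epithelial members were 8 and 1 (11 and 1 over the list alone), with Ehf at 1.36, the matriptase St14 at 1.24 and Ocln, a tight junction gene, at 1.15, and surface markers were 7 and 0 (8 and 0 over the list alone). The mesenchymal list had a median of 0.10 with 3 members higher and 2 lower and was not called (adjusted p = 0.716). Of 7 macrophage and blood cell markers 2 rose and 0 fell, and of 11 endothelial markers 3 rose and 0 fell, with neither list called (camera, adjusted p = 0.308 each). Of 78 small nucleolar, nuclear and Y RNA genes 13 were lower (class median -0.24), against 710 of 13149 genes that are not predicted, short RNA or ribosomal protein genes. The epithelial call ended without day 9 CD73- (0.0753) and that of the surface markers without day 6 CD49d+ (0.253), and both ended without the day term (0.094). Over all alternatives the adjusted p of the 3 ran from 9.05e-06, 0.000152 and 0.000242 up to 0.968.

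Between the 2 poised populations few genes passed, and those with the largest differences did not. Tnc was 9.41-fold higher in CD49d+ than in CD73+ cells (± 0.493 log2 units, adjusted p = 0.061), Acta2 8.78-fold (± 0.33, adjusted p = 0.0587), and Crabp1 8.06-fold (log2 3.01 ± 0.214, adjusted p = 0.0587). Postn was 5.4-fold (adjusted p = 0.0621) and the sphingosine phosphate receptor S1pr3 4.74-fold (adjusted p = 0.0704), none past the threshold. Acta2 had log2 intensities of 12.34 and 11.60 in CD49d+ cells, 8.86 and 8.81 in CD73+ cells and 11.14 and 11.44 in CD73- cells at days 6 and 9. On the lower side Mctp1, a membrane calcium sensor, passed (2.59-fold, log2 -1.37 ± 0.0797, adjusted p = 0.0407), and the synthase subunit Atp5l (-1.64, adjusted p = 0.0587), the mannosidase Man1c1 (-1.53), the exchange factor Psd3 (-1.45) and Crybg1 (-1.44) did not. In limma 4 genes passed, and the other 3, chosen after their values were seen, were A630089N07Rik (-1.69, adjusted p = 0.00825), the small RNA gene Scarna2 (0.94, adjusted p = 0.0407) and Gabra2, at the floor in CD49d+ cells (-1.01, adjusted p = 0.0407). There were 3212 genes at an unadjusted p under 0.05, and 27 higher and 19 lower genes differed at least 2-fold at both days, with 0.448 and 0.345 for independent lists, 2 opposite and r = 0.58 across genes. The count of passing genes depends on the setting: 719 with quantile normalization (70.7% higher, against 25% as deposited), and 694 with centring (42.8% higher). There were 352 with a trended robust prior, 342 among genes above the floor on all 8 arrays, a fit chosen after the data were seen, and 285 with the 75th percentile filter. There were 160 without the day term, 1 without a filter and 0 on the 6 sorted arrays. It was 0 in limma without any 1 of the 8 arrays, with 1687 to 3038 genes at an unadjusted p under 0.05.

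Mesenchymal and fibroblast genes were higher in CD49d+ than in CD73+ cells as a list, with a median of 0.53 over 44 genes (camera, adjusted p = 0.00309; adjusted p = 0.952 with an estimated correlation). Limma called 0 members over all genes and 3 higher (Acta2, Postn, Bgn) and 1 lower (Tbx15) adjusted over the list alone, with 19 higher and 2 lower at an unadjusted p under 0.05. By day, over all 46 genes of the list, the median was 0.67 at day 6 (18 genes at least 2-fold higher, 0 lower) and 0.16 at day 9 (7 higher, 1 lower). Markers of other cell types differed in places, with 0 members passing over all genes and neither list called. Adjusted over the list alone, 3 of 7 macrophage and blood cell markers were higher and 0 lower (adjusted p = 0.202), and 3 of 11 endothelial markers were higher and 1 lower (adjusted p = 0.207). Glycolysis genes were called higher (median 0.23, adjusted p = 0.03; adjusted p = 0.952 with an estimated correlation), with 0 members over all genes and Aldoc when adjusted over the list alone, and 7 higher and 1 lower at an unadjusted p under 0.05. The mesenchymal call ended without the day 6 CD49d+ array (adjusted p = 0.585). The glycolysis call ended without day 6 unsorted (0.0888), day 9 CD49d+ (0.26), day 9 CD73+ (0.188) or day 9 unsorted (0.0608), under quantile normalization (0.111, with a median of 0.26 where that of all tested genes moved from 0.00744 to 0.057) and without the day term (0.0616). Over all alternatives the adjusted p ran from 1.91e-11 for the mesenchymal and 0.000127 for the glycolysis list up to 0.952.

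CD73+ cells differed from the unsorted cells of the same days in both directions. The Y RNA Rny3 was at least 15.2-fold lower, being at the floor in CD73+ cells (adjusted p = 0.00302). Tnc was 14.5-fold lower (log2 -3.86 ± 0.493, adjusted p = 0.0128), Acta2 12.7-fold (-3.67 ± 0.33, adjusted p = 0.0092), Efemp1 11.6-fold and the protease inhibitor Serpinb9b 10.3-fold (adjusted p = 0.008). The adhesion molecule Ceacam1 was 7.03-fold higher (2.81 ± 0.443, adjusted p = 0.0176), Crybg3 5.62-fold, Klk1 5.29-fold (adjusted p = 0.0492), the noncoding RNA Snhg14 5.23-fold and Trh 5.21-fold. At both days 143 genes were at least 2-fold higher and 169 lower (4.26 and 5.05 for independent lists; r = 0.87 across genes). In limma 2951 genes passed, 1519 higher and 1432 lower, with 5127 at an unadjusted p under 0.05, and 35.4% were higher under quantile normalization against 51.5%. The count was 0 in limma without day 6 CD73+, day 6 unsorted, day 9 CD73+ or day 9 unsorted, 1956 without day 6 CD73-, 1823 without day 9 CD73-, 2660 without day 6 CD49d+ and 2740 without day 9 CD49d+. Without a filter 1940 passed.

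Epidermal genes were lower in CD73+ than in unsorted cells (median -0.70 over 20 genes; camera, adjusted p = 7.47e-07; adjusted p = 0.718 with an estimated correlation). Of them 0 were higher and 12 lower (0 and 15 adjusted over the list alone), including the cornified envelope gene Sprr1a (-2.98) and the basal keratin Krt14 (-2.10). In the same contrast 22 of 78 small nucleolar, nuclear and Y RNA genes were lower (class median -0.19). Mesenchymal genes were lower too (median -0.90; adjusted p = 2.4e-05; adjusted p = 0.92 with an estimated correlation), with 3 higher and 19 lower (4 and 28 over the list alone), including the surface glycoprotein Thy1 (-2.74) and the collagen Col1a1 (-2.35). Trophoblast genes were lower (median -0.53, 0 higher and 5 lower, 0 and 6 over the list alone; adjusted p = 0.0314; adjusted p = 0.718 with an estimated correlation). DNA and histone modifiers were higher (median 0.20, 7 higher and 0 lower, 9 and 0 over the list alone; adjusted p = 0.00248; adjusted p = 0.92 with an estimated correlation), with Tet2 at 1.47 and Jarid2 at 0.98. The trophoblast call ended without day 6 CD73+ (0.136) or day 6 unsorted (0.076) and under quantile normalization (0.0542, with a median of -0.65 where that of all tested genes moved from -0.0166 to -0.0882), over a range of 0.0127 to 0.718, and the other 3 were kept without any 1 array.

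CD49d+ cells had higher Trh (11.7-fold, log2 3.55 ± 0.54, adjusted p = 0.0367), Tgm3 (7.24-fold), Itga4 (6.51-fold, 2.70 ± 0.165, adjusted p = 0.0085), Bmx (5.99-fold) and Gpr50, an orphan receptor (4.93-fold), than unsorted cells. The epidermal genes Sprr1a (12.6-fold, -3.66 ± 0.231, adjusted p = 0.0085), Cnfn (8.47-fold) and Krtdap (8.42-fold, -3.07 ± 0.229), with Serpinb9b (8.27-fold) and Rny3 (7.17-fold), were lowest. At both days 104 genes were at least 2-fold higher and 75 lower (2.25 and 2.28 for independent lists; r = 0.60 across genes). In limma 585 genes passed, 350 higher and 235 lower, with 2870 at an unadjusted p under 0.05. The count was 3 without day 6 CD49d+, 10 without day 6 CD73+, 183 without day 6 CD73- and 0 without day 6 unsorted. It was 31 without day 9 CD49d+ or day 9 CD73+, 91 without day 9 CD73- and 4 without day 9 unsorted. With centring 1005 passed, without the day term 336 and without a filter 323.

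Epidermal genes had a median of -1.19 in CD49d+ against unsorted cells (camera, adjusted p = 9.14e-12; adjusted p = 0.451 with an estimated correlation), with 0 higher and 11 lower (1 and 14 adjusted over the list alone). Beside them 21 of 78 small nucleolar, nuclear and Y RNA genes were lower (class median -0.30). Mesenchymal genes had a median of -0.37 (adjusted p = 0.00395; adjusted p = 0.951 with an estimated correlation), with 0 and 2, both ways of adjusting. FGF-ERK response genes were higher (median 0.36, adjusted p = 0.00445; adjusted p = 0.951 with an estimated correlation), with 1 and 0 (6 and 0 over the list alone). DNA and histone modifiers were higher (median 0.11, adjusted p = 0.00106; adjusted p = 0.951 with an estimated correlation), with 4 and 0 (6 and 0 over the list alone). The mesenchymal direction turned without day 9 CD49d+ (adjusted p = 0.689) and its call ended without day 9 unsorted (0.682). The FGF-ERK call ended without day 6 CD49d+ (0.295) or day 6 unsorted (0.228), and that of the modifiers without day 9 CD49d+ (0.0529) or day 9 unsorted (0.074). Over all alternatives the adjusted p ran from 8.1e-13, 2.29e-05 and 1.27e-05 for these 3 lists up to 0.951.

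Between CD73- and unsorted cells more genes passed as lower than as higher. Rny3 (14.5-fold, log2 -3.86 ± 0.124, adjusted p = 0.0033), Serpinb9b (13.8-fold, -3.79 ± 0.19, adjusted p = 0.00662), the matrix protein gene Prelp (7.88-fold, -2.98 ± 0.16), the keratin Krt90 (at least 7.14-fold, at the floor in CD73- cells) and Sprr1a (6.76-fold) were lowest. Cbln2 was 2.08-fold higher (1.06 ± 0.1, adjusted p = 0.0299), while Fndc3c1 (1.57, adjusted p = 0.101), the linker histone H1f1 (1.42, adjusted p = 0.0797) and the Ras pathway scaffold Cnksr2 (1.06, adjusted p = 0.0817) did not pass. At both days 5 genes were at least 2-fold higher and 95 lower (0.0535 and 1.67 for independent lists; r = 0.67 across genes). In limma 136 genes passed, 28 higher and 108 lower (20.6% higher, against 47% with centring and 31.1% with quantile normalization), with 3264 at an unadjusted p under 0.05. The count was 13 without day 6 CD49d+, 12 without day 6 CD73+, 21 without day 9 CD49d+, 13 without day 9 CD73+ and 0 without day 6 CD73-, day 6 unsorted, day 9 CD73- or day 9 unsorted. It was 757 with centring, 386 with quantile normalization, 361 with a trended robust prior, 327 with the 75th percentile filter, 317 among genes above the floor on all 8 arrays and 52 without a filter.

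The unsorted arrays serve all 3 of these contrasts, so part of the overlap on 1 day may come from shared arrays. On different days, CD73+ at day 6 and CD73- at day 9, each minus unsorted, shared 82 genes at least 2-fold lower and 12 higher (2.56 and 1.14 for independent lists). CD73+ at day 9 and CD73- at day 6 shared 64 lower and 2 higher (3.31 and 0.201).

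In CD73- against unsorted cells 11 lists were called. Epidermal genes were lower (median -0.79; camera, adjusted p = 4.21e-12; adjusted p = 0.434 with an estimated correlation), with 0 higher and 7 lower (0 and 17 adjusted over the list alone). Of 78 small nucleolar, nuclear and Y RNA genes 12 were lower (class median -0.12). Epithelial genes were lower (median -0.26, adjusted p = 2.93e-06; adjusted p = 0.485 with an estimated correlation), with 0 and 4 (0 and 11 over the list alone): the claudin Cldn4 (-1.36), the simple epithelial keratins Krt8 (-1.26) and Krt19 (-0.75), and Dsp (-0.71). Lower without a member passing over all genes were mesenchymal (adjusted p = 0.00113; 2 lower over the list alone), TGF-beta response (adjusted p = 0.042; 1 lower) and endothelial lists (adjusted p = 0.049; 0). So were surface markers (adjusted p = 0.049; 1 higher, Fut9, and 3 lower). Cell cycle S phase (adjusted p = 0.00238; 0 over the list alone), G2 and M phase (adjusted p = 0.00274; 1 lower, Rangap1) and DNA and histone modifiers (adjusted p = 0.000499; 1 higher, Suz12) were higher. At an unadjusted p under 0.05 limma gave 12 lower mesenchymal, 6 lower and 1 higher TGF-beta, 1 lower endothelial and 7 lower and 1 higher surface genes. At the same threshold there were 11 higher S phase, 8 higher and 1 lower G2 and M phase and 11 higher modifier genes. Each of these 7 lists had adjusted p = 0.8 with an estimated correlation. Immediate early and heat shock genes (adjusted p = 0.00714; 4 lower over the list alone; adjusted p = 0.731 with an estimated correlation) and neural genes (adjusted p = 0.042; 2 lower over the list alone; adjusted p = 0.631 with an estimated correlation) were lower. The epidermal, epithelial and modifier calls were kept without any 1 array. Without day 9 unsorted the other 8 ended (adjusted p 0.489 mesenchymal, 0.814 TGF-beta, 0.107 S phase and immediate early, 0.489 G2 and M phase and endothelial, 0.0614 neural, 0.507 surface markers). Without day 6 CD73- all of these but immediate early ended (0.0565 to 0.205). TGF-beta, endothelial and surface marker calls also ended without day 6 CD73+ (0.0524 to 0.0617) and the first 2 without day 9 CD73+ (0.0527 and 0.0619). The endothelial call ended without day 9 CD73- (0.208) and the neural call without day 6 unsorted (0.121), and quantile normalization ended TGF-beta, neural, endothelial and surface marker calls (0.0715 to 0.09), with medians of -0.38, -0.22, -0.21 and -0.28 under it, where that of all tested genes moved from 0 to -0.0347. Leaving out the day term ended the surface marker call (0.163). Over all alternatives the adjusted p ran from 2.72e-13 for epidermal, 1.07e-07 for epithelial and 3.98e-05 for modifier genes, and from 0.0219 for the neural list, up to the estimated-correlation values, except that the TGF-beta list reached 0.814.

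**Figure D3:**
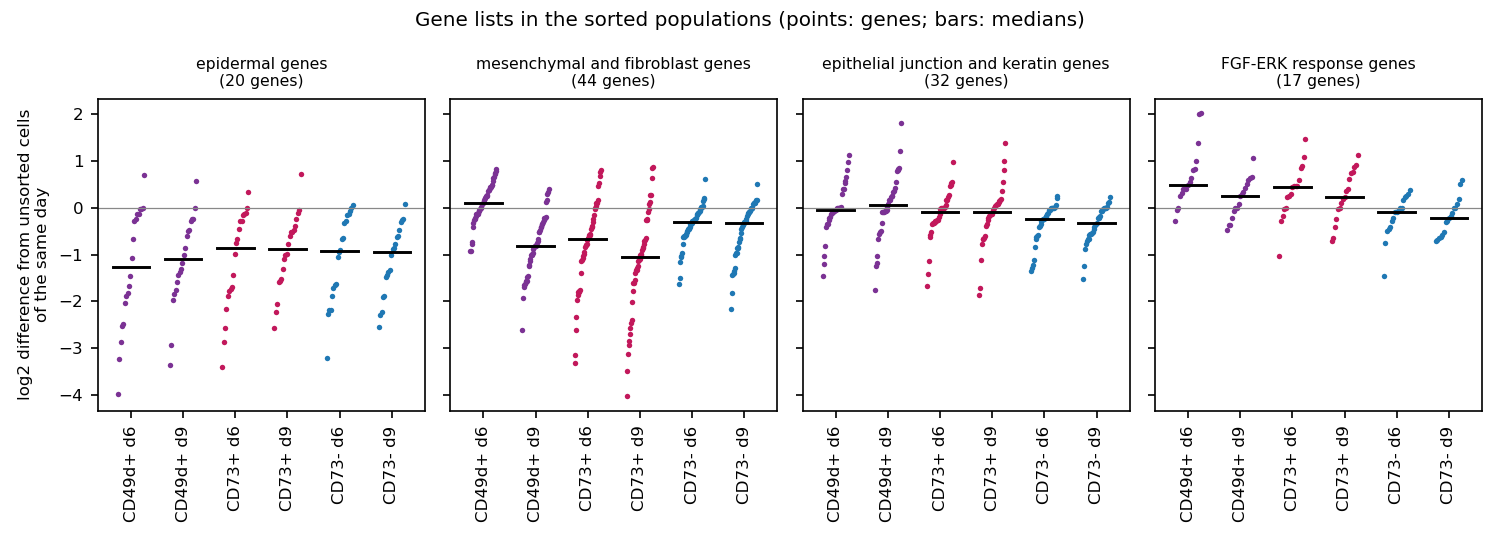
Points are genes of 4 lists, with the vertical axis the log2 difference of each sorted array from the unsorted array of the same day, and bars are list medians. Epidermal medians lie below 0 on all 6 sorted arrays, and the mesenchymal median of CD49d+ cells lies above 0 at day 6 and below it at day 9.

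Between day 6 and day 9, fitted over the 4 populations together, lists shifted while no single gene passed. The spread here is the disagreement of the day difference among the 4 populations, which are not replicates of a day. Any difference in culture or handling between the days cannot be told apart from day, whatever the p-values. Epithelial junction and keratin genes were higher at day 9 (median 0.28; camera, adjusted p = 7.99e-18; adjusted p = 0.221 with an estimated correlation), with 16 members higher and 0 lower adjusted over the list alone. Among them were Ehf at 1.28 ± 0.158 (adjusted p = 0.114), St14 at 1.06 (adjusted p = 0.114) and the adhesion molecule Epcam at 0.96 (adjusted p = 0.156). Surface markers (adjusted p = 2.05e-07; 10 higher over the list alone, Itgb4 at 1.13 and Alpl at 1.17; adjusted p = 0.352 with an estimated correlation) were higher. So were FGF-ERK response genes (adjusted p = 1.1e-06; 3 higher, with Dusp6 at 0.81 and Spry4 at 0.63; adjusted p = 0.498 with an estimated correlation). Epidermal genes were higher as well (adjusted p = 2.43e-06; 6 higher, with Krt17 at 1.24 and Gsta4 at 0.92; adjusted p = 0.287 with an estimated correlation). Of 42 pluripotency network genes only the 29 above the floor on some of the 8 arrays were tested. These were higher (camera, adjusted p = 0.000781, and adjusted p = 0.287 with an estimated correlation), with 5 higher over the list alone. Among them Utf1 stood at 0.91 (adjusted p = 0.114), L1td1 at 0.81 (adjusted p = 0.093) and the F-box gene Fbxo15 at 0.69 (adjusted p = 0.14). Neural genes (adjusted p = 0.00474; 0 over the list alone; adjusted p = 0.287 with an estimated correlation) and interferon response genes (adjusted p = 0.0122; 0 over the list alone; adjusted p = 0.791 with an estimated correlation) were higher. Oxidative phosphorylation genes were lower (median -0.06, adjusted p = 0.00474; 0 over the list alone; adjusted p = 0.666 with an estimated correlation). The populations did not all follow these directions. The median change of interferon response genes was -0.30 in CD49d+ cells against 0.38 in CD73+, 0.42 in CD73- and 0.14 in unsorted cells. In CD49d+ cells the median was 0.01 for FGF-ERK response genes and for oxidative phosphorylation genes and 0 for surface markers, and it was 0 for pluripotency genes in CD73+ cells. In CD73- cells it was 0.00 for pluripotency genes and 0.01 for epidermal genes.

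Among interferon, neural and oxidative phosphorylation genes 2 and 4 higher and 4 lower had an unadjusted p under 0.05. Limma called 0 of 13313 genes between the days, with 1545 at an unadjusted p under 0.05, a smallest adjusted p of 0.0926 and 0 genes at least 2-fold apart one way in all 4 populations. Krt8 stood at 0.72 and Meox2 at -1.23 (adjusted p = 0.093). The count was 151 with centring, 43 among genes above the floor on all 8 arrays, 8 with the 75th percentile filter and 5 with quantile normalization, and 0 in limma without any 1 array (758 to 2111 at an unadjusted p under 0.05). The interferon call ended without day 6 CD73+ (0.379), day 6 CD73- (0.174), day 6 unsorted (0.113), day 9 CD73+ (0.36), day 9 CD73- (0.195) or day 9 unsorted (0.0622), over a range of 9.01e-08 to 0.791, while the other 7 calls were kept without any 1 array.

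The control arrays, 1 each and without a test, spanned the change from fibroblast to stem cell. ESC exceeded MEF at least 72.7-fold in the Nodal co-receptor Tdgf1, at least 50.2-fold in Nanog and 40.3-fold in Utf1. It exceeded MEF at least 38.3-fold in Sox2, 36.3-fold in Fgf4, 32.1-fold in Zfp981, 30.1-fold in the glycine decarboxylase Gldc and in Zscan4e, 28-fold in the glucose transporter Slc2a3 and at least 27.1-fold in Dppa2. The matrix genes Aspn (at least 60.9-fold), Ogn (46.2-fold), Thbs2 (39.9-fold), Fbln5 (38.8-fold), decorin (Dcn, 36.9-fold), Ccn3 (at least 35.8-fold), the collagenase Mmp13 (at least 34.5-fold), the zinc finger gene Osr1 (28.7-fold), C1qtnf3 and dermatopontin (Dpt, at least 28.5-fold each) were lower in ESC. Of 14301 genes 1715 were at least 2-fold higher in ESC and 1708 lower. Pluripotency network genes had a median of 3.15 (percentile 100 among random lists), with 38 of 42 at least 2-fold higher and 0 lower, S phase genes 1.92 and epithelial genes 1.44 (percentile 100 each). Mesenchymal genes had -2.81 (percentile 0), with 0 higher and 40 of 46 lower.

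SC4 had low fibroblast genes, and its stem cell network genes lay far below ESC. Against MEF it was at least 53.1-fold higher in Cyp2b23, 47.1-fold in Klk1 and 41.2-fold in Nr0b1, 45.8-fold higher in the cornified envelope gene Sprr2b, and at least 35.5-fold in Gna14 and 29.5-fold in Slc35f2. It was at least 106-fold lower in Thbs1, 102-fold in Acta2, 85.7-fold in Postn, 84.3-fold in lysyl oxidase (Lox), 75.6-fold in Thbs2 and 70.9-fold in Tnc. Against ESC it was at least 72.7-fold lower in Tdgf1, 62.4-fold in Acta2, 50.2-fold in Nanog, 47.1-fold in the transporter Slc38a4 and 38.3-fold in Sox2, and 37.6-fold lower in Utf1. It was at least 47.1-fold higher than ESC in Klk1, 40.3-fold in the cystine transporter Slc7a11, 34.5-fold in the chromatin remodeller Smarca2 and 29.9-fold in the laminin Lama4, and 47-fold and 34.4-fold higher in Sprr2b and Cd109. Genes at least 2-fold apart numbered 1567 higher and 1641 lower against MEF and 775 and 1057 against ESC. The mesenchymal median was -3.46 against MEF (percentile 0), with 0 of 46 genes higher and 38 lower, and the S phase median 1.83 with 36 of 39 higher. The pluripotency median was 0.06 against MEF (percentile 95.31, 18 higher and 2 lower) and -1.71 against ESC (percentile 0, 3 higher and 29 lower), and the epithelial median 0.03 (percentile 90.2) and -1.10 (percentile 0).

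On the way from MEF to ESC, genes lost from fibroblasts were further along than genes gained in ESC. A MEF-higher gene at the floor both on an array and in ESC counts as 100%. An ESC-higher gene at the floor both on an array and in MEF counts as 0%. Of ESC-higher genes 31.01% lay at the floor in MEF. On the reprogramming arrays 19.3% (day 9 unsorted) to 22.18% (day 6 CD73+ and CD73-) did. The floor may thus widen the gap between the sets, by an amount not measured here. Over 544 genes at least 4-fold higher in MEF, CD73+ cells stood at 91.5% (83.3 to 95.9) at day 6 and 92.2% (87.5 to 97.6) at day 9 of the distance to ESC. CD49d+ cells stood at 72.7% (68.3 to 75.9) and 87.2% (82.4 to 91) and CD73- cells at 83.4% (79.1 to 88) and 74.3% (71.1 to 78.8). Unsorted cells stood at 71.4% (68.3 to 75.3) and 64.9% (61.2 to 67.8), and SC4 at 100% (100 to 100). That interval without width may reflect genes at the floor in both SC4 and ESC. Over 487 genes at least 4-fold higher in ESC, the 8 reprogramming arrays lay between 44.4% (36.1 to 50.1; day 9 unsorted) and 59.6% (51.1 to 67.3; day 9 CD49d+), with overlapping intervals among the 3 sorted populations at day 6, and SC4 at 65.2% (57.2 to 70.8). These percentages have no replicate, and they move with the threshold: over genes at least 8-fold higher in ESC the day 6 positions ran from 18.6% in CD73- to 30.1% in CD73+ cells. Over genes at least 2-fold apart the gap between gene sets narrowed, with unsorted cells of day 6 at 67.9% for MEF-higher and 62.8% for ESC-higher genes and CD73- cells of day 9 at 71.1% and 64.9%. The position over ESC-higher genes does not measure gain of the stem cell network. The pluripotency list median lay 0 to 0.01898 log2 units above MEF on the 8 reprogramming arrays, against 3.147 in ESC. Of its 42 genes 16 lay above the floor in MEF and 21 (day 6 CD73-) to 26 (day 9 unsorted) on these arrays. A median near 0 thus reflects members at the floor and does not show that no member rose. Nr0b1 had 12.22 in day 9 CD49d+ cells against 6.644 in MEF, while Tdgf1 had 6.644 in both. The S phase median lay 1.487 to 1.816 above MEF on the 8 reprogramming arrays, against 1.922 in ESC.

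**Figure D4:**
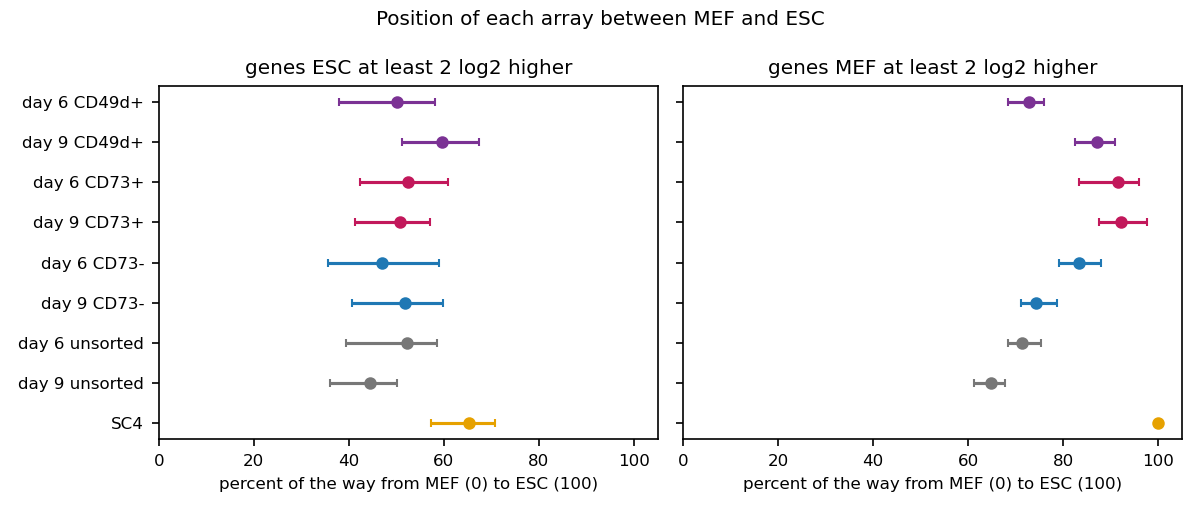
Points are the median percent of the way from MEF (0) to ESC (100) of each array, for 487 genes higher in ESC (left) and 544 higher in MEF (right), and bars are 95% rank intervals across genes. For MEF-higher genes CD73+ cells lie at 91.5 and 92.2 and unsorted cells at 71.4 and 64.9, and SC4 lies at 100. Genes at the floor both on an array and in ESC count as 100 on the right. Genes at the floor both on an array and in MEF count as 0 on the left.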

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

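The tests of explanations in this part were chosen after the results they address were seen, while the camera tests without 1 array and the scalings they draw on were planned. Several differences ran opposite ways at day 6 and day 9, and these differences between days were not tested. The median of the mesenchymal and fibroblast genes in CD49d+ minus CD73- cells was 0.4686 at day 6 and -0.2335 at day 9. The median of the interferon response genes in CD49d+ minus CD73+ cells was 0.4326 at day 6 and -0.3485 at day 9. Among single interferon genes, Ifi27 stood at 1.219 and -1.409 in CD49d+ minus CD73- cells, and in CD49d+ minus CD73+ cells Oasl2 stood at 1.114 and -1.199 and Usp18 at 1.342 and -1.032. A different question, the interaction of pooled poised against CD73- cells with day, takes the difference of CD49d+ and CD73+ cells within a day as its spread. A true difference between these cells counts as error there, so few calls say little. The interaction does not test these reversals within the poised cells or in CD49d+ cells alone. Fitted on the 6 sorted arrays with 2 residual degrees of freedom, it called 0 of 12973 genes in limma, with 408 at an unadjusted p under 0.05 and a smallest adjusted p of 1.

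Few of the probe sets that the comparisons did not use were higher in poised cells, and these were picked by that pattern. Of 16010 probe sets with no gene symbol, 2 (0.0125%) were at least 2-fold higher on all 4 poised arrays than on both CD73- arrays and MEF. Of 1814 probe sets with several symbols, 2 (0.11%) were as well. Both shares are below the 58 of 23521 (0.247%) among probe sets with 1 symbol. The brighter of the unnamed probe sets had log2 intensities of 11.59 and 11.58 in day 6 CD49d+ and CD73+ cells, 7.09 in day 6 CD73- cells, 11.76 in SC4 and 6.64, the floor, in ESC.

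Epidermal genes lay lower in each sorted population than in unsorted cells. Under quantile normalization and median centring the highest of the list medians was -0.726. Centring moved no array by more than 0.0684 log2 units, so it could not have brought the list near 0. These values argue only against scaling differences that quantile normalization removes. Unsorted cells as a blend of CD73+ and CD73- cells alone are argued against by the pattern itself rather than by a separate test, since a mixture of 2 parts cannot exceed both. At the day with the lower value the median gene exceeded the higher of the pair by 0.79 log2 units, and 7 of 20 epidermal genes exceeded both by at least 1 unit at both days, against 53 of 14301 genes. A stress response to sorting stays open: the highest median of immediate early and heat shock genes in sorted minus unsorted cells was -0.0906 (-0.375 to 0.0557), which is no rise but does not exclude other responses. Cells lost in the sort, or a difference in handling, may remain as hypotheses, and a biological difference between the gates and the rest of the culture was not tested.

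Mesenchymal genes lay higher in CD49d+ than in CD73+ cells, with a list median of 0.67 at day 6 and 0.16 at day 9, and the call ended without the day 6 CD49d+ array (adjusted p = 0.585, in a range of 1.91e-11 to 0.952). The lower of the list medians under quantile normalization and centring was 0.514. Since centring moved no array by more than 0.0684 log2 units, these values argue only against scaling differences that quantile normalization removes. Fibroblasts with the MEF profile left in the day 6 CD49d+ gate stay open: the 12 mesenchymal genes used imply a median share of 11.2% (0.203% to 48.3%), and 11 of 50 MEF genes needed far less than that share (under 1/4), among them Aspn (2.26%), Ccn3 (0.463%) and Mmp13 (0%), while Acta2 needed 48.3%. These 50 are the brightest MEF genes among those at least 16-fold above the day 6 CD73+ array. The MEF array need not show how fibroblasts look after the factors, so these values do not decide. Slower loss of fibroblast genes in CD49d+ cells is a biological candidate explanation that was not tested.

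Short RNA genes lay lower in sorted cells. Of 78 such genes, 11 (14.1%) were lower on all 6 sorted arrays than on all 5 others, against 95 of 14223 other genes (0.668%), where chance gives 0.216% (one-sided Fisher exact p = 1.12e-11 across genes, which are not independent). Loss of short RNAs in sorting or RNA preparation may be a source, but the class median of day 6 CD73- cells was -0.0696 and that of MEF, which are unsorted, -0.623, so the class did not move as one and the question stays open. Rny3 had log2 values of 10.51 and 10.63 in unsorted cells and at most 7.88 on the sorted arrays. No biological explanation was tested.

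Other splits of the 8 arrays cannot be used to judge the count of 0 genes between day 9 and day 6, since any split calls at least 0. Thus 35 of 35 splits into 4 and 4 without the population block, and 8 of 8 assignments of day with it, called as many by construction. With the block the real value was 0 and the highest other 0, and 8 are too few for a share under 0.05. Without it the real value was 0 and the highest other 770, in the split that parts the 4 poised arrays from CD73- and unsorted cells. Another, which parts CD49d+ and unsorted from CD73+ and CD73- cells, called 579, while the third that keeps populations whole, CD49d+ and CD73- against CD73+ and unsorted cells, called 0. The first pair points to a structure of the samples that follows some groupings of the populations.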

How the results depend on the processing

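Among these alternatives, the fit to genes above the floor on all 8 arrays was chosen after the data were seen. Of 239 named gene results 0 reversed, where a change of sign counted only if the gene passed in the main fit or in the alternative. Changes of sign in genes that passed in neither were not counted. Other settings gave 1899 values on the same side of the threshold, 106 stronger and 49 weaker, and leaving out 1 array gave 1353, 16 and 538. The ranked genes among them were chosen for a large difference in the same direction at both days. Their direction was thus largely fixed by the choice, so for these genes the count of 0 does not test it. Of 44 called lists, other settings kept 111 values and weakened 65, and leaving out 1 array kept 275, weakened 76 and reversed 1, the mesenchymal list in CD49d+ minus unsorted cells without the day 9 CD49d+ array (adjusted p = 0.689, in a range of 8.1e-13 without day 6 CD49d+ to 0.951 with an estimated correlation). The 6 sorted arrays give no value for contrasts with unsorted cells, and for the day limma called 0 genes on them, with 962 at an unadjusted p under 0.05 and a smallest adjusted p of 0.273. The day block pairs the populations of a day. Values at the floor of 100 hide falls below it, so folds against a floor are lower bounds, and signal over the floor limits dim genes. Leaving out an array changes the number of residual degrees of freedom. Leaving out the filter changes only the number of genes adjusted over, so it does not test dim probe sets. For the other moves the cause was not tested.

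The counts of genes that passed, in the order poised, CD73+ and CD49d+ minus CD73- and CD49d+ minus CD73+, then CD73+, CD49d+ and CD73- minus unsorted, were 1599, 1065, 1777, 4, 2951, 585 and 136. Without a filter they were 994, 497, 1007, 1, 1940, 323 and 52. Centring gave 1735 for CD73+ minus CD73-, 694 for CD49d+ minus CD73+, 1005 for CD49d+ minus unsorted, 757 for CD73- minus unsorted and 151 for the day (0 as deposited). Quantile normalization gave 719 for CD49d+ minus CD73+, 386 for CD73- minus unsorted and 5 for the day, and the 75th percentile filter 285, 327 and 8. The trended robust prior gave 352 and 361 for the first pair of these, and genes above the floor on all 8 arrays 342, 317 and, for the day, 43. The 6 sorted arrays gave 616 for CD73+ minus CD73-, 1183 for CD49d+ minus CD73- and 0 for CD49d+ minus CD73+. Without the day block CD73+ minus CD73- had 612, CD49d+ minus CD73+ 160 and CD49d+ minus unsorted 336. With 1 array left out the ranges were 1 to 1775, 0 to 1009, 1 to 1203, 0 to 0, 0 to 2740, 0 to 183 and 0 to 21, and 0 to 0 for the day.

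Lists called numbered 4, 8, 3, 2, 4, 4 and 11 in that order and 8 for the day. With an estimated correlation camera called 0 in each of the 8. Since it then uses only 3 residual degrees of freedom, this does not show an effect of correlated members. In CD73+ minus CD73- cells the trophoblast call (camera, adjusted p = 0.0265) ended too (0.997), with an estimated correlation of -0.0341. Without the day block the first 4 had 2, 5, 1 and 1, and quantile normalization left 3 in CD73+ minus CD73-, 1 in CD49d+ minus CD73+ and 7 in CD73- minus unsorted. With 1 array left out they ran from 2 to 7, 2 to 7, 2 to 8, 1 to 7, 3 to 5, 2 to 10, 3 to 12 and 7 to 15.

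Genes past 2-fold one way at both days numbered 245, 281, 270, 46, 312, 179 and 100. At 1.5-fold they were 727, 802, 791, 266, 1146, 504 and 318, and at 3-fold 60, 70, 63, 6, 77, 39 and 32. For ESC minus MEF, SC4 minus MEF and SC4 minus ESC, 3423, 3208 and 1832 became 5889, 5503 and 3872 at 1.5-fold and 1637, 1631 and 799 at 3-fold.

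Positions over ESC-higher genes past 3 log2 units were 25.9, 30.1, 18.6 and 25.9 for day 6 CD49d+, CD73+, CD73- and unsorted cells, 39, 34.9, 36.2 and 35 at day 9, and 47 for SC4. Past 1 log2 unit they were 64.5, 63.7 and 62.8 for day 6 CD73+, CD73- and unsorted cells and 58.4 and 64.9 for day 9 CD73+ and CD73- cells. Over MEF-higher genes past 1 log2 unit they were 65.8, 77.6 and 67.9 for day 6 CD49d+, CD73+ and unsorted cells, 78.4, 77.4 and 71.1 for day 9 CD49d+, CD73+ and CD73- cells, and 98.2 for SC4. Past 3 log2 units CD73- cells had 77.6 and 68.9.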

Other observations

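All tests in this part were chosen after the results were seen. Of 42 pluripotency network genes, 23, 22, 21 and 22 lay above the floor in day 6 CD49d+, CD73+, CD73- and unsorted cells and 25, 24, 22 and 26 at day 9, with 16 in MEF, 28 in SC4 and 42 in ESC. Nanog was at the floor except in day 9 CD73- cells (log2 7.385), day 9 unsorted cells (6.90) and ESC (12.29). Tdgf1, Zfp42 and Esrrb were above the floor in ESC alone (12.83, 10.58 and 8.93). Nr5a2 had 8.70 in day 9 CD49d+ and 7.33 in day 9 CD73+ cells, the floor in CD73- and unsorted cells, 11.04 in SC4 and 9.81 in ESC. Utf1 had 9.98 in day 9 CD73- cells, 9.11 and 8.98 in day 9 CD49d+ and CD73+ cells, 7.32 in SC4 and 12.55 in ESC.

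A hypothesis from these data is that poised cells may share part of the SC4 profile rather than that of ESC. For the 123 genes at least 2-fold higher in both poised populations at both days, which are the 121 of the report and 2 predicted genes, C730036E19Rik and F830045P16Rik, the median SC4 minus ESC difference was 0.741, at percentile 100 among random lists matched on expression, with 56 genes at least 2-fold higher in SC4 and 7 lower. Their median ESC minus MEF difference was 0 (percentile 49.55). For the 36 genes at least 2-fold lower in both, the median SC4 minus ESC difference was -0.7, at percentile 0, with 3 higher and 14 lower. Against MEF their SC4 median was -0.174 (percentile 6.67, 1 higher and 10 lower), which does not lie beyond the random lists, while that of the 123 was 1.04 (percentile 100). SC4 is 1 array of a line of unstated origin relative to these cells, so these values leave open why they resemble each other.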
